A study of Schizosaccharomyces pombe with 261 samples.

How the data were processed

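The series has 261 samples, and the 39 mRNA-seq libraries, 13 groups of 3, were used: WT of series RNA1 at 0, 5 and 25 min at 37.5 °C, WT of series RNA2 at 0, 2.5 and 5 min, and series RNA3 with the labels atf1Δ and pcr1Δ at 0 and 5 min and clr4Δ at 0, 2.5 and 5 min. The 198 ChIP-seq and 24 PRO-seq samples were not analysed here. Per the labels, cells were grown at 30 °C and moved to 37.5 °C, RNA was taken by hot phenol, and libraries were made with a KAPA mRNA HyperPrep kit. Groups, times and genotypes were read from the sample titles and labels. The labels number the replicates 1 to 3 and do not say whether they were separate cultures.

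The authors give Trimmomatic 0.33, Bowtie 0.12.9, bedtools 2.17.0, deepTools and STAR in their processing notes, with build ASM294v2. The main table holds counts per gene that the authors made with STAR, 1 column per library, with the STAR summary lines. Which strand column was taken is not stated, so values of genes that overlap on opposite strands are uncertain. The second table deposited by the authors, for the 18 libraries of WT of series RNA2 and the label clr4Δ, was described as counts. The values deposited by the authors behave as a coverage signal, the read depth at each base summed over the gene, and not as read counts: in libraries of both tables the median was 49.8 units of signal per count. Reads that map to several places appear to be included, which was not tested. Gene names and products came from a reference annotation of a later build, and positions from the second table. Of 6845 genes matched to the annotation, 29.2% had the same start and end in both, so positions are given for ASM294v2 only.

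Counts of 7015 gene identifiers were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 6172. Library sizes were scaled by TMM. All 39 libraries were fitted together with a mean per group (26 residual degrees of freedom), and each comparison was a quasi-likelihood F-test (2-sided) with Benjamini-Hochberg adjustment over all genes tested, called at adjusted p under 0.05. WT at 5 min was the mean of the contrasts within series RNA1 and RNA2, and deletion responses were tested as differences between contrasts. WT was the mean of both series at 0 and 5 min and series RNA2 alone at 2.5 min. No WT library belongs to series RNA3, so label and series are confounded in every comparison with WT, of levels at 0 min and of responses to heat. Comparisons between its own strains share the series name, though its libraries may differ in other ways. The second table was planned for edgeR as counts. Since its unit is a signal, limma-trend (limma 3.58.1) was used instead, on log2 of the TMM-scaled signal plus 50, for 6150 genes with a mean signal of at least 500 and without the ribosomal RNA genes. CPM are counts per 1000000 counts in genes, with TMM scaling.

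Gene lists were written from general knowledge of the organism, before the data were examined, and matched by name (subtelomeric genes by the cosmids in their identifiers, ribosomal proteins by symbol): chaperones (26 of 28 names matched), the Atf1-dependent core stress response (30), trehalose and glycerol metabolism (10), oxidative stress enzymes and Pap1 targets (24), cytosolic ribosomal proteins (140), ribosome biogenesis and RNA polymerase I (37 of 40), proteasome (31 of 40), subtelomeric genes (104, of which 50 tested), genes under Mmi1 and Red1 (15), mating (15), nitrogen starvation (14), Tf2 (13, of which 3 tested), histones (10), MBF (17 of 18), iron uptake (12), phosphate uptake (5), heterochromatin and RNAi (24) and mitochondrially encoded genes (11, of which 10 tested). Some genes are in several lists. Each list with 5 or more tested genes was tested with camera in limma, with a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the lists within a comparison. Counts of genes that rose or fell in a list are given with adjustment over all genes and, in brackets, over the list alone.

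Genes named with values followed a rule: atf1, pcr1, clr4, ura4 and ade6 in every comparison, the largest changes each way (10 in the main comparisons, 5 in the others) among genes with adjusted p under 0.05 and a mean of at least 10 CPM, and the 4 members of each list with the smallest p. Except in the response differences, the largest changes were also required to show no overlap between libraries of the compared groups. With 3 libraries a side, no overlap, in either direction, arises by chance for 10% of genes. Genes outside this rule (meu6, SPNCRNA.1362, and the centromeric long non-coding RNAs) were chosen after the values were seen.

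Depth ran from 6573143 to 12588425 counts in genes per library. Reads mapping to several places were 6.80 to 21.2% of reads, reads outside genes 1.19 to 2.49%, unmapped reads 0.200 to 0.993% and ambiguous reads 0.709 to 1.37%. All pairs of replicates differed by more than counting noise (lowest chi-squared per degree of freedom 5.47). The test was also tested on simulated data with the depths and spreads of these libraries: at 2-fold it recovered 95.5% of changed genes for WT at 5 min, 90.6% for WT at 2.5 min and 89.6% for the clr4Δ response difference at 5 min. Camera called 0 of 100 simulated lists of 30 unchanged genes. Genes were simulated independently of each other, so these lists could not show how camera behaves where genes of a list move together. Whether equal replicate numbers pair across times was checked by the correlation of their deviations from group means. It was 0.247 to 0.482 in series RNA1, 0.174 to 0.554 in RNA2, 0.211 to 0.473 for clr4Δ, 0.101 to 0.272 for pcr1Δ, and -0.075 at the lowest for atf1Δ, where 0.1 was required. For atf1Δ, number 1 gave 0.464, but replicate 3 at 0 min correlated with replicate 2 at 5 min (0.412). Unequal numbers reached 0.207 in RNA2. For pcr1Δ, numbers 2 and 3 gave 0.101 and 0.111, no higher than an unequal pair (0.111). Counts that use the numbers as a block or unit are thus uncertain for atf1Δ and pcr1Δ. Numbers were checked only within a strain and series, so block results for 0 min differences between them are uncertain too.

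Alternatives chosen before the data were examined were DESeq2 size factors in edgeR, library totals alone, no filter, a filter at a mean of 10 CPM, DESeq2 (1.42.0) Wald tests, fits of the contrasted groups alone, leaving out each library, the replicate number as a block, a single WT series, and the other deletions as reference. Leaving out the 3 libraries with the highest share of ribosomal RNA, and pseudocounts of 5 and 500 on the signal, were chosen after seeing the data. For chance groupings, libraries (or numbered replicates with their times as a unit, for response differences) were split in every other way, or in 99 other ways drawn at random where there were more. Contrasts that share control libraries were set against 20 simulations with no effect. Early and later genes, called in series RNA2, were compared in their response difference from WT of series RNA1 alone, with 100000 permutations within 5 strata of the WT rise at 5 min. Other steps used Python 3.11 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.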

Results

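The series follows fission yeast (Schizosaccharomyces pombe) through the first minutes at 37.5 °C after growth at 30 °C. The part reported here is polyadenylated mRNA measured by sequencing in 39 libraries, in 13 groups of 3. Series RNA1 holds wild type (WT) at 0, 5 and 25 min of heat, and series RNA2 holds WT at 0, 2.5 and 5 min. Series RNA3 holds libraries labelled atf1Δ and pcr1Δ at 0 and 5 min and libraries labelled clr4Δ at 0, 2.5 and 5 min. Atf1 and Pcr1 are bZIP transcription factors that act as a pair in the stress response, and Clr4 is the methyltransferase that marks heterochromatin on histone H3 lysine 9. Total counts in genes ran from 6573143 to 12588425 per library. The 10 most counted genes took 8.45 to 10.52% of the counts in the libraries of series RNA1, and 5.97 to 7.36% in those of series RNA2. In series RNA3 they took 6.50 to 7.59% in the libraries labelled clr4Δ and 8.48 to 10.56% in those labelled atf1Δ or pcr1Δ. The other 222 of 261 samples, which are ChIP-seq and PRO-seq, were not analysed here.

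Changes are log2 values with their standard error (SE), with 3 libraries in each group and thus 6 WT libraries at 0 min and 6 at 5 min where both series were used. A gene is said to have risen or fallen where its adjusted p from edgeR was under 0.05, and positions refer to build ASM294v2. The p-values measure only the spread between libraries, because the labels do not say whether replicates were separate cultures.

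The deleted genes themselves were measured in every group. Counts of atf1 (SPBC29B5.01, chromosome II, 1546194 to 1549862) in WT were 131 ± 14.2 counts per 1000000 (CPM; mean and SD, n = 3) at 0 min, 718 ± 31.1 at 5 min and 437 ± 34.4 at 25 min in series RNA1. In series RNA2 they were 213 ± 8.65 at 0 min, 294 ± 45.5 at 2.5 min and 572 ± 55.4 at 5 min. In the libraries labelled atf1Δ they were 128.5 ± 12.4 at 0 min and 168 ± 6.66 at 5 min, so reads were still assigned to the gene. Counts of pcr1 (chromosome I, 4252142 to 4253622) in the libraries labelled pcr1Δ were 42.3 ± 4.84 CPM at 0 min and 53.3 ± 2.73 at 5 min, against 64.1 ± 8.98 and 363 ± 35.2 in WT of series RNA1. Counts of clr4 (chromosome II, 453996 to 458487) were higher, not lower, in the libraries labelled clr4Δ: 175 ± 4.16 CPM at 0 min, 153 ± 8.40 at 2.5 min and 110 ± 10.4 at 5 min. WT had 51.1 ± 1.90 CPM at 0 min in series RNA1 and 43.7 ± 0.849 in series RNA2. The genotype in the labels also places copies of ura4 (chromosome III, 115589 to 116726) and ade6 (chromosome III, 1316291 to 1318035) in the repeats of centromere 1. In the libraries labelled clr4Δ at 0 min, ura4 was higher than in WT by 1.15 ± 0.08 and ade6 by 0.56 ± 0.09.

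**Figure D1:**
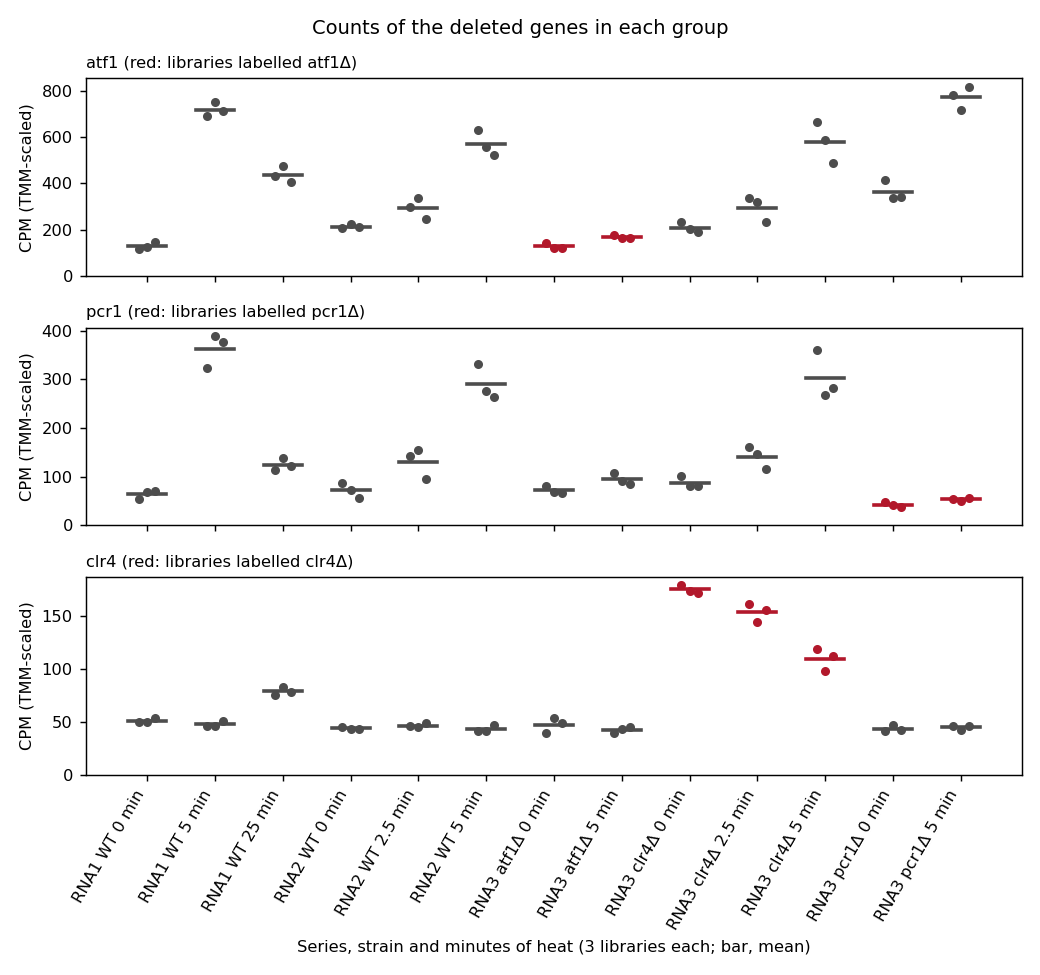
Counts per 1000000 (CPM) of atf1, pcr1 and clr4 (y axis) in each of the 39 libraries, by group (x axis), with the group mean as a bar and the libraries labelled as the deletion of that gene in red. Counts of clr4 lie between 43 and 78.6 CPM on average in WT groups and between 110 and 175 CPM in the groups labelled clr4Δ.

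The first comparison asked what 5 min of heat does to mRNA levels in WT. Genes of protein folding were among those with large rises: ssa1, an Hsp70 chaperone, by 5.90 ± 0.21, hsp104, which dissolves protein aggregates, by 5.63 ± 0.22, and the small heat shock protein gene hsp16 by 5.39 ± 0.30. Of the 26 chaperone genes tested, 22 rose and 1 fell, with the same numbers when adjusted over the list alone and a median of 1.18. Of 30 genes of the Atf1-dependent core stress response, 25 rose and 2 fell, also when adjusted over the list alone, with a median of 1.98. Among them pyp2, the phosphatase that switches off the stress kinase Sty1, rose by 4.68 ± 0.22, the transcription factor gene rsv2 by 4.30 ± 0.20, and ntp1, a trehalase, by 2.63 ± 0.10. The transcription factor genes themselves rose, atf1 by 1.94 ± 0.09 (adjusted p = 1.62e-18) and pcr1 by 2.26 ± 0.12 (adjusted p = 1.79e-17). The largest rises of all included 2 genes whose products the annotation leaves without a function, wwm3 (7.36 ± 0.29) and smp4 (4.95 ± 0.21), beside rtc3 of the SBDS family (5.53 ± 0.19).

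Of 10 genes of trehalose and glycerol metabolism, 8 rose and 1 fell, among them tps1, which makes trehalose phosphate (2.40 ± 0.14), and gpd1, which makes glycerol phosphate (2.01 ± 0.11). Of 24 genes for oxidative stress enzymes, 13 rose and 2 fell, among them the catalase gene ctt1 (3.19 ± 0.18), the sulfiredoxin gene srx1 (2.36 ± 0.14) and the glutathione peroxidase gene gpx1 (2.05 ± 0.12). All 31 proteasome subunit genes rose, by a median of 0.37. In the other direction, 32 of 37 genes of ribosome biogenesis and RNA polymerase I fell, among them noc201 (-1.22 ± 0.10) and imp4 (-1.34 ± 0.13). These 4 counts were the same when adjusted over each list alone. The largest falls were those of the F-box gene pof15 (-3.07 ± 0.13), of dbp3, an RNA helicase (-2.28 ± 0.13), and of the phosphate transporter gene pho84 (-1.95 ± 0.19).

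In the set test (camera), chaperones (adjusted p = 2.11e-34), the Atf1-dependent list (2.29e-22) and trehalose and glycerol genes (1.8e-09) moved up relative to other genes, and all 3 calls held with an estimated correlation. The other 3 calls did not hold: oxidative stress enzymes (adjusted p = 8.9e-05; adjusted p = 0.0543 with an estimated correlation), proteasome (2.13e-07; adjusted p = 0.0645 with an estimated correlation) and ribosome biogenesis (6.26e-10; adjusted p = 0.187 with an estimated correlation). In total 1587 genes rose and 1537 fell at 5 min, of 6172 tested, with 388 and 111 of them changed by at least 2-fold. Series RNA2 alone gave 873 higher and 805 lower, and series RNA1 alone gave 2988 changed genes. Under library totals alone the median of all genes was -0.168 (-0.007 in the main fit) and the calls split into 991 higher and 2520 lower.

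**Figure D2:**
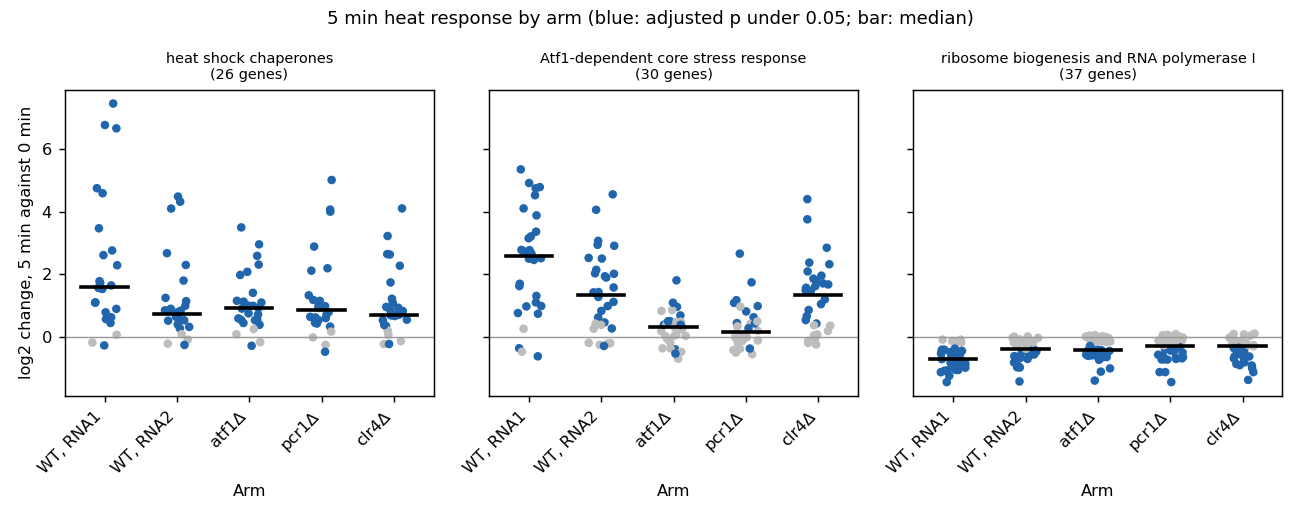
Log2 change from 0 to 5 min of heat (y axis) for each gene of 3 lists in 5 arms (x axis: WT of series RNA1, WT of series RNA2, and the libraries labelled atf1Δ, pcr1Δ and clr4Δ), blue where adjusted p was under 0.05 and grey otherwise, with the median as a bar. The median of the Atf1-dependent list was 2.59 in series RNA1, 1.35 in series RNA2, 0.30 in the libraries labelled atf1Δ and 0.15 in those labelled pcr1Δ.

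At 2.5 min, measured in series RNA2 only, the question was which genes move first. Early rises were those of wwm3 (5.04 ± 0.45), smp4 (2.65 ± 0.28), rtc3 (2.54 ± 0.24), rsv2 (2.23 ± 0.27), hsp104 (2.23 ± 0.27) and ssa1 (2.07 ± 0.25). Of the 26 chaperone genes 6 rose, or 11 when adjusted over the list alone, and of the 30 Atf1-dependent genes 7 rose, or 12 when adjusted over the list alone. The transcription factor genes had risen by then, pcr1 by 0.86 ± 0.16 (adjusted p = 0.134 in a fit of these groups alone) and atf1 by 0.47 ± 0.12 (adjusted p = 0.0468). The atf1 call was lost with library totals (0.123), DESeq2 size factors (0.0535), a fit of these groups alone (0.149) and without the 3 libraries with the highest share of ribosomal RNA (0.058). It was also lost without replicate 1, 2 or 3 at 0 min (0.157, 0.099 and 0.161) or replicate 1 or 2 at 2.5 min (0.182 and 0.374). The largest fall was that of nar1, annotated as an iron hydrogenase (-1.39 ± 0.17). In the set test the chaperone call (adjusted p = 2.59e-19) held with an estimated correlation (0.0215). The call of the Atf1-dependent list (1.43e-10) did not (adjusted p = 0.251 with an estimated correlation), nor did those of trehalose and glycerol genes (0.00796; 0.562), oxidative stress enzymes (0.0132; 0.371), ribosome biogenesis (1.9e-04; 0.679) and proteasome (5.52e-04; 0.371), where the value after each semicolon is the adjusted p with an estimated correlation. In total 70 genes rose and 37 fell. That count was 483 with the replicate number as a block, 32 from a fit of these groups alone and 71 with library totals. It was 48 and 49 without replicate 2 or 1 at 2.5 min, 168 without replicate 3 at 2.5 min, and 49 and 58 without replicate 2 or 3 at 0 min.

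From 2.5 to 5 min the same groups went on rising. Between these times cta3, a calcium pump gene, rose by 3.14 ± 0.35, pyp2 by 2.85 ± 0.27, hsp16 by 2.81 ± 0.38, hsp104 by 2.26 ± 0.26 and ssa1 by 2.25 ± 0.25. Of the chaperone genes 19 of 26 rose (21 when adjusted over the list alone), and of the Atf1-dependent genes 18 of 30 rose (23 rose and 1 fell when adjusted over the list alone). Both set tests held with an estimated correlation (0.00926 and 0.0211). Of the ribosome biogenesis genes 12 of 37 fell (17 when adjusted over the list alone), a set call (3.03e-08) that was lost with an adjusted p = 0.239 with an estimated correlation. Of 24 heterochromatin and RNAi genes 1 rose and 6 fell (1 and 7 when adjusted over the list alone), among them clr1 (-0.72 ± 0.10) and chp1 (-0.58 ± 0.11), both of silencing complexes; the set call (0.00422) was lost with an adjusted p = 0.172 with an estimated correlation. In total 458 genes rose and 376 fell, against 308 and 457 with library totals alone. The count of 834 was 1557 with the replicate number as a block, 273 from a fit of these groups alone, 477 without replicate 1 at 5 min and 509 without replicate 3 at 2.5 min.

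By 25 min of heat, measured in series RNA1 only, more genes had changed in WT: 4156, against 2988 at 5 min in this series. Stress genes with large rises were hsp16 by 8.70 ± 0.50, lsd90 by 8.68 ± 0.53, hsp9, a heat shock protein gene, by 6.52 ± 0.41, the metallothionein gene zym1 by 5.35 ± 0.20 and gpx1 by 4.17 ± 0.18, all against 0 min. Of the chaperone genes 22 of 26 rose and 3 fell, and of the Atf1-dependent genes 24 of 30 rose and 2 fell, with medians of 1.62 and 2.72. The machinery of growth fell: 135 of 140 cytosolic ribosomal protein genes, by a median of -0.995, and all 37 genes of ribosome biogenesis and RNA polymerase I, by a median of -1.61, among them gar1 (-2.55 ± 0.13) and rpa43 (-2.26 ± 0.12). Of 17 genes of G1/S under MBF, 14 fell and 2 rose, among them mik1, an inhibitor of mitosis (-2.83 ± 0.15), and cdc22, of ribonucleotide reductase (-1.51 ± 0.13). All of these counts were the same when adjusted over each list alone.

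Among the smaller groups at 25 min, 10 of 14 genes of nitrogen starvation and stationary phase rose, among them mug14 (3.74 ± 0.21) and the autophagy gene atg8 (1.15 ± 0.09). Phosphate uptake genes fell in 4 of 5 cases, among them pho84 (-2.77 ± 0.27), and 7 of 10 histone genes fell while 1 rose. Of 15 meiotic genes under Mmi1 and Red1, which remove their transcripts, 8 rose, and of 3 Tf2 retrotransposon genes tested 1 rose (Tf2-2, 1.03 ± 0.28), too few for a set test. The set test called chaperones up (6.51e-19), and this held with an estimated correlation (0.0238). With an estimated correlation these other calls gave adjusted p values over 0.05: Atf1-dependent genes (9.28e-15; 0.0674), ribosome biogenesis (2.01e-22; 0.0521), ribosomal proteins (1.05e-14; 0.362), MBF genes (0.00174; 0.174), trehalose and glycerol genes (3.17e-05; 0.151), oxidative stress enzymes (0.00163; 0.151), proteasome (2.48e-04; 0.174) and nitrogen starvation (0.00911; 0.186). Histones (0.122), phosphate uptake (0.0644) and the genes under Mmi1 and Red1 (0.357) were not called. In total 2090 genes rose and 2066 fell, with 851 and 673 changed by at least 2-fold. Long non-coding RNAs took 1.19 to 1.30% of the counts at 25 min, against 0.700 to 0.902% at 0 min in this series.

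Set against 5 min, 25 min separated transient from lasting rises. The level of wwm3 changed by -4.88 ± 0.32 between these times, that of pyp2 by -4.33 ± 0.29, and those of srx1, pcr1 and atf1 by -2.42 ± 0.20, -1.55 ± 0.16 and -0.72 ± 0.12. Meanwhile zym1 rose further by 3.73 ± 0.18 and lsd90 by 3.32 ± 0.41. Of the Atf1-dependent genes 18 rose further and 7 fell back, and of the chaperone genes 9 rose and 8 fell (11 and 8 when adjusted over the list alone). Ribosomal protein genes fell in this interval in 135 of 140 cases and rose in 1, and histone genes fell in 9 of 10, among them hht1 (-1.19 ± 0.09). The set calls of ribosomal proteins (1.57e-23) and histones (6.18e-04) each gave an adjusted p = 0.26 with an estimated correlation. Of the 873 genes that were higher at 5 min in series RNA2, which shares no library with this contrast, 293 were lower and 262 higher at 25 than at 5 min. In total 1755 genes were higher and 1829 lower at 25 than at 5 min; with library totals alone the median of all genes was 0.267 (0.007 in the main fit) and the split was 2767 and 1069. Since 5 and 25 min share their 0 min libraries, overlaps of those lists were set against simulated counts. The changes at 5 and 25 min correlated across genes at r = 0.711, against 0.346 with no effect simulated. With the 0 min libraries divided between the contrasts r was 0.553. The simulated r comes from noise alone and is not a share of the observed r. The covariance, which keeps the size of the changes, was 0.574, against a mean of 0.0124 in the simulations.

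The next question was how much of the 5 min response needs Atf1 and Pcr1. In the libraries labelled atf1Δ or pcr1Δ the chaperone genes still rose with heat: 22 of 26 rose and 1 fell in each (23 and 1, and 22 and 2, when adjusted over the list alone), with medians of 0.91 and 0.86. The gene hsp104 rose by 3.50 ± 0.28 in the libraries labelled atf1Δ and by 4.07 ± 0.29 in those labelled pcr1Δ, and fes1, an Hsp70 cofactor, by 2.08 ± 0.11 and 2.19 ± 0.11. Of the 30 Atf1-dependent genes, 8 rose and 2 fell in the libraries labelled atf1Δ (10 and 3 when adjusted over the list alone), and 10 rose and 1 fell in those labelled pcr1Δ (10 and 2 when adjusted over the list alone). The exceptions included rsv2, which rose by 1.81 ± 0.26 and 2.66 ± 0.27. Ribosome biogenesis genes fell in 22 and 19 of 37 cases, and proteasome genes rose in 26 and 23 of 31 cases (30 and 26 when adjusted over the list alone). Heterochromatin and RNAi genes fell in 11 and 8 of 24 cases, among them clr1 (-1.08 ± 0.10 and -0.98 ± 0.09) and epe1 (-1.18 ± 0.12 and -0.89 ± 0.12), and 2 rose in each. The chaperone set calls held with an estimated correlation (0.00147 and 0.00107), as did the proteasome call in the libraries labelled atf1Δ (0.0408). Those lost gave an adjusted p with an estimated correlation of 0.0819 for proteasome in the libraries labelled pcr1Δ, 0.602 and 0.595 for ribosome biogenesis, 0.137 and 0.479 for heterochromatin genes, and 0.988 for the Atf1-dependent list in those labelled pcr1Δ. In total 778 genes rose and 1068 fell in the libraries labelled atf1Δ, and 771 rose and 920 fell in those labelled pcr1Δ. With the replicate number as a block the totals were 2817 and 2648, and without the 3 libraries with the highest share of ribosomal RNA the total of 1846 for those labelled atf1Δ was 1212. Under library totals alone the medians of all genes were -0.181 and -0.107 (-0.008 and -0.004 in the main fit), with splits of 320 and 1707 and of 410 and 1178.

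Whether the responses differed was tested directly, as the change with heat in the deletion libraries minus that in WT. In the libraries labelled atf1Δ the difference was -7.87 ± 0.52 for wwm3, -5.57 ± 0.30 for rtc3 and -4.63 ± 0.36 for smp4, and in those labelled pcr1Δ it was -7.58 ± 0.50, -5.36 ± 0.30 and -4.38 ± 0.37. Of the 30 Atf1-dependent genes, 21 had a lower response in each (22 lower and 1 higher when adjusted over the list alone), by medians of -1.66 and -1.56. Among them were pyp2 (-3.58 ± 0.35 and -3.50 ± 0.35), ntp1 (-1.95 ± 0.17 and -1.82 ± 0.17) and ish1, of the nuclear envelope (-3.71 ± 0.36 and -3.80 ± 0.36). The list also holds the deleted genes, whose own smaller response is counted in it. This difference was -1.555 for atf1 in the libraries labelled atf1Δ and -1.925 for pcr1 in those labelled pcr1Δ. At 0 min, counts of atf1 with the label atf1Δ (128.5 CPM) were near those of WT of series RNA1 (130.5) and below series RNA2 (213.3). The response of atf1 itself differed by -0.86 ± 0.15 in the libraries labelled pcr1Δ (-0.34 against WT of series RNA2 alone, adjusted p = 0.799), and that of pcr1 differed by -1.87 ± 0.20 in those labelled atf1Δ. Trehalose and glycerol genes had a lower response in 6 of 10 cases in each (6 and 7 lower, and 1 higher in each, when adjusted over the list alone), among them gpd1 (-1.76 ± 0.19 and -1.90 ± 0.19). Oxidative stress enzymes did so in 6 and 8 of 24 cases, the same when adjusted over the list alone, among them ctt1 (-3.02 ± 0.31 and -3.10 ± 0.31) and gpx1 (-2.24 ± 0.25 and -2.44 ± 0.26). Chaperone genes had a lower response in 12 and 11 of 26 cases (14 and 12 when adjusted over the list alone), among them ssa1 (-2.94 ± 0.30 and -1.89 ± 0.30). This rested on series RNA1: against its WT alone 19 and 20 of the 26 were lower (medians -0.680 and -0.847), while against WT of series RNA2 alone at most 1 was (medians 0.11 and 0.08), with ssa1 in the libraries labelled pcr1Δ at -0.32. In those labelled atf1Δ ssa1 rose by 2.96, against 4.32 in WT of series RNA2. Of the Atf1-dependent genes 24 and 24 were lower against series RNA1 alone and 14 and 13 against series RNA2 alone. The same references gave 7 and 3 (atf1Δ) and 8 and 3 (pcr1Δ) for trehalose and glycerol genes, and 8 and 3 and 9 and 4 for oxidative stress enzymes. Responses were higher for pho84 (1.72 ± 0.31 and 1.44 ± 0.31), which fell in WT, though against WT of series RNA2 alone it was at 1.06 (adjusted p = 0.182) and 0.775 (0.642), and for pof15 (1.85 ± 0.22 in the libraries labelled pcr1Δ).

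Of the 388 genes that rose at least 2-fold in WT at 5 min, 198 rose in the libraries labelled atf1Δ and 221 in those labelled pcr1Δ, and 223 and 202 had a lower response. In total 490 genes had a lower and 63 a higher response in the libraries labelled atf1Δ, and 395 a lower and 49 a higher one in those labelled pcr1Δ. The numbers with a higher response were unstable: they were 223 and 162 without replicate 3 of series RNA2 at 5 min, and as few as 39 and 29 without 1 other library. The set calls of the Atf1-dependent list (5.16e-39 and 4.68e-38) held with an estimated correlation (0.00176 and 0.00207), as did those of trehalose and glycerol genes (0.027) and oxidative stress enzymes (0.0231) in the libraries labelled pcr1Δ. Those lost gave an adjusted p with an estimated correlation of 0.151 and 0.194 for chaperones, and of 0.0672 for trehalose and glycerol genes and 0.109 for oxidative stress enzymes in the libraries labelled atf1Δ. Against WT of series RNA2 alone, 123 genes were lower and 5 higher in the libraries labelled atf1Δ and 117 lower and 9 higher in those labelled pcr1Δ; against WT of series RNA1 alone the totals were 994 and 1016. With the replicate number as a block they were 1107 (825 lower, 282 higher) and 1088 (735 lower, 353 higher), and without the 3 libraries with the highest share of ribosomal RNA the total of 553 was 307.

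The losses in the libraries labelled atf1Δ and pcr1Δ were shared for many genes. Across genes the differences from WT correlated at r = 0.812, and 341 genes were lower in both, where 31.4 would be lower in both if the lists were independent. Both differences use the same WT libraries, which alone gave r = 0.347 in simulated counts with no effect. That r comes from noise alone, so it is not a share of the observed r. The covariance, which keeps the size of the changes, was 0.222, against a mean of 0.0255 in the simulations. With the WT libraries divided, series RNA1 for atf1Δ and series RNA2 for pcr1Δ, r was 0.484 and 115 genes were lower in both, against 14.5 if independent. Tested against each other, the responses differed for 2 genes, both lower in the libraries labelled atf1Δ: SPNCRNA.1548, a long non-coding RNA (chromosome II, 2764286 to 2765303; -1.05 ± 0.17, adjusted p = 0.00563), and gsf1 (-0.90 ± 0.17, adjusted p = 0.0268). In all 117 genes had an unadjusted p under 0.05, DESeq2 and library totals each called 4, a fit of these groups alone 7, and the fit with the replicate number as a block 11. The count fell to 1 without the 3 libraries with the highest share of ribosomal RNA. Leaving out 1 library gave 0 for replicate 2 at 0 or 5 min labelled atf1Δ and for replicate 3 at 0 min or replicate 1 at 5 min labelled pcr1Δ. It gave 1 for replicate 3 at 0 or 5 min labelled atf1Δ and for replicate 1 at 0 min or replicate 2 or 3 at 5 min labelled pcr1Δ. In simulated counts for this comparison the test recovered 34.8% of 1.5-fold, 80.3% of 2-fold and 97% of 4-fold differences. For hsp16 the difference was -2.43 ± 0.52 (adjusted p = 0.0883), with an adjusted p of 3.19e-04 with the block, 0.0234 with DESeq2, 0.0266 with library totals, 0.0107 in a fit of these groups alone, 0.0319 without replicate 1 at 0 min labelled atf1Δ and 0.825 without the 3 libraries with the highest share of ribosomal RNA.

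The libraries labelled clr4Δ were heated to ask whether the H3 lysine 9 methyltransferase changes the response. At 5 min they showed the groups seen in WT: wwm3 rose by 6.38 ± 0.39, pyp2 by 4.41 ± 0.30, hsp104 by 4.11 ± 0.29 and atf1 by 1.47 ± 0.13. Of the chaperone genes 21 of 26 rose and 1 fell (21 and 2 when adjusted over the list alone), and of the Atf1-dependent genes 21 of 30 rose (22 rose and 1 fell when adjusted over the list alone), with medians of 0.70 and 1.34. The reads assigned to clr4 fell by 0.67 ± 0.08. The chaperone call held with an estimated correlation (0.0107) and that of the Atf1-dependent list (2.5e-16) did not (adjusted p = 0.0624 with an estimated correlation). At 2.5 min wwm3 rose by 4.26 ± 0.40 and hsp104 by 2.18 ± 0.27, with 8 chaperone genes (11 up and 1 down when adjusted over the list alone) and 5 Atf1-dependent genes risen (10 when adjusted over the list alone). The chaperone call at 2.5 min held (0.033), and that of the Atf1-dependent list (4.37e-10) was lost with an adjusted p = 0.281 with an estimated correlation. In total 1001 genes rose and 864 fell at 5 min, against 642 and 1018 with library totals alone, and 1063 changed in a fit of these groups alone. At 2.5 min 56 rose and 41 fell. That count of 97 was 582 with the replicate number as a block, 156 with DESeq2 and 55 from a fit of these groups alone. It was 58 and 51 without replicate 1 or 2 at 0 min and 40 without replicate 2 at 2.5 min, and without replicate 3 at 0 min 34 rose and 57 fell.

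Tested against WT of both series, the 5 min response of the libraries labelled clr4Δ was lower for ddr48 (-2.88 ± 0.51), hsp16 (-2.76 ± 0.45) and ssa1 (-2.67 ± 0.30), and for 11 of 26 chaperone genes (18 when adjusted over the list alone). It was also lower for 6 of 30 Atf1-dependent genes (18 lower and 1 higher when adjusted over the list alone). Against WT of series RNA2 alone, 1 gene was called in all, and ddr48, hsp16 and ssa1 were at -0.58, -1.47 and -1.10, not called. Against WT of series RNA1 alone 846 genes were called. The chaperone set call held with an estimated correlation (0.00719), and that of the Atf1-dependent list (4.63e-12) gave an adjusted p = 0.114 with an estimated correlation. These calls rested on series RNA1: against its WT alone 20 of 26 chaperone genes (median -0.895) and 21 of 30 Atf1-dependent genes were lower, with 1 higher, while against WT of series RNA2 alone the medians were -0.03 and -0.08. The mitochondrially encoded genes, a sign of RNA quality, had a median difference of 4.04 in this comparison (0.0199; adjusted p = 0.551 with an estimated correlation). For the libraries labelled atf1Δ and pcr1Δ it was 2.20 (0.21) and 0.67 (0.68). These genes had few counts and single libraries stood out. They took 0.0078% of the counts in replicate 3 labelled clr4Δ at 5 min, against 0.001 and 0.0006% in replicates 1 and 2. In WT of series RNA1 at 0 min replicate 3 had 0.0156%, against 0.0004% in replicates 1 and 2. In total 142 genes were lower and 20 higher, a count of 162 that was 900 (541 lower, 359 higher) with the replicate number as a block, 81 with library totals, 50 from a fit of these groups alone and 95 without the 3 libraries with the highest share of ribosomal RNA. Leaving out 1 library gave 265 and 97 for replicates 3 and 1 of series RNA2 at 5 min, 107 for replicate 3 of series RNA1 at 0 min, 101 and 95 for replicates 1 and 2 labelled clr4Δ at 0 min, and 249 and 64 for replicates 1 and 3 labelled clr4Δ at 5 min. At 2.5 min edgeR called 0 genes different between the libraries labelled clr4Δ and WT of series RNA2, with 74 at an unadjusted p under 0.05, and DESeq2 also called 0. In simulated counts for that comparison edgeR recovered 46.3% of 1.5-fold, 72.3% of 2-fold and 86.2% of 4-fold differences. The clr4 difference at 2.5 min was -0.27 ± 0.12 (adjusted p = 1.00).

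Before heat, at 0 min, the libraries labelled atf1Δ and pcr1Δ differed from WT in genes of mating. Of 15 genes of mating and meiosis entry, 8 were higher in the libraries labelled atf1Δ, and 6 were higher and 1 lower in those labelled pcr1Δ, also when adjusted over the list alone. These included the pheromone receptor gene map3 (3.24 ± 0.11 and 2.47 ± 0.11), the transcription factor gene map1 (2.95 ± 0.18 and 2.72 ± 0.18) and ste11, the regulator of sexual differentiation (1.51 ± 0.16 and 1.19 ± 0.16, the latter 0.28 and no longer called against the other deletions of series RNA3). Among Atf1-dependent genes the directions were mixed: 12 were higher and 10 lower in the libraries labelled atf1Δ (15 and 10 when adjusted over the list alone) and 11 were higher and 11 lower in those labelled pcr1Δ (12 and 11 when adjusted over the list alone). For instance fbp1, of gluconeogenesis, was higher by 2.33 ± 0.10 and 2.18 ± 0.10, while gpx1 differed by -3.70 ± 0.19 and -3.77 ± 0.19. In the libraries labelled pcr1Δ the median of that list was 0.28, its mean -0.08 and its set test up (0.863). The largest differences were those of mug153 (6.34 ± 0.24 and 6.12 ± 0.24) and of eno102, an enolase gene (-6.64 ± 0.88 and -6.73 ± 0.86). Against the other deletions of series RNA3, eno102 was at -4.23 ± 2.55 and -4.35 ± 2.55, no longer called. Chaperone genes were higher in 19 and 15 of 26 cases, and 1 was lower in the libraries labelled atf1Δ. Iron uptake genes were higher in 7 of 12 cases and lower in 2 in each, among them str3, a siderophore transporter gene (5.01 ± 0.36 and 4.64 ± 0.35). The gene atf1 was higher in the libraries labelled pcr1Δ by 1.13 ± 0.10.

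The mating set calls at 0 min (2.28e-08 and 4.99e-06) held with an estimated correlation (3.56e-04 and 0.00239). Those of chaperones (1.35e-09 and 1.02e-04) gave an adjusted p with an estimated correlation of 0.155 and 0.44, and those of iron uptake (0.00155 and 0.00282) gave 0.31 and 0.44. In total 1400 genes were higher and 1347 lower in the libraries labelled atf1Δ, and 1180 higher and 1183 lower in those labelled pcr1Δ, of which 1005 were higher and 1013 lower in both. If the lists were independent 268 and 258 would be shared, and with the WT libraries divided between the comparisons 623 and 669 were. No WT library belongs to series RNA3, so each comparison with WT also crosses series. A reference of the other deletions of series RNA3 keeps the series name fixed, but those deletions and library differences within the series enter it. With it, 1412 genes differed for the libraries labelled atf1Δ and 972 for those labelled pcr1Δ. Of these, 1220 and 757 were also called against WT. Chaperone genes were higher in 13 and 5 of 26 cases against WT of series RNA2 alone, and 2 were lower in the libraries labelled pcr1Δ.

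In the libraries labelled clr4Δ at 0 min, genes near chromosome ends were higher. Of 50 subtelomeric genes tested, 30 were higher and 4 lower than in WT (32 and 4 when adjusted over the list alone), by a median of 0.96. The helicase gene tlh2 (chromosome II, 4526885 to 4532899) was higher by 6.36 ± 0.21, SPBCPT2R1.07c by 7.65 ± 0.46 and ftm4 by 4.63 ± 0.38. The set call (5.63e-21) held with an estimated correlation (2.59e-07). Against WT of series RNA2 alone, 19 of the 50 were called higher, by a median of 0.72. Against the mean of both WT series, stress and iron genes were higher as well. The gene ssa1 was higher by 2.70 ± 0.20, cta3 by 2.74 ± 0.28 and shu1, of haem uptake, by 3.56 ± 0.39. So were 16 of 26 chaperone genes (18 when adjusted over the list alone), 16 of 30 Atf1-dependent genes (18) and 8 of 12 iron uptake genes (8). A single chaperone gene and a single iron uptake gene were lower. Of 10 histone genes 8 were higher, also when adjusted over the list alone. Against WT of series RNA2 alone far fewer were called: 2 chaperone genes, 4 Atf1-dependent genes, 2 iron uptake genes and 1 histone gene, with medians of 0.09, 0.33, 0.59 and 0.18. With that reference ssa1 was higher by 1.60, and against the other deletions of series RNA3 by 0.45, no longer called. These calls gave an adjusted p with an estimated correlation of 0.138 for chaperones, 0.236 for Atf1-dependent genes, 0.138 for iron uptake and 0.236 for histones. In total 884 genes were higher and 635 lower. The count of 1519 was 1012 from a fit of these groups alone, 2316 against series RNA1, 230 against series RNA2, 3116 against the other deletions of series RNA3, and 827 without replicate 1 labelled clr4Δ.

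Repeats of the centromeres, which heterochromatin covers, are read in the second table, whose coverage signal appears to include reads that map to several places. Of 14 centromeric long non-coding RNAs tested there, 13 were higher in the libraries labelled clr4Δ at 0 min than in WT of series RNA2. They were picked as a class after the values were seen. The signal of SPNCRNA.371 (chromosome II, 1636393 to 1636776) was higher by 8.45 ± 0.49 (limma, adjusted p = 1e-09), that of SPNCRNA.231 by 7.96 ± 0.57 and that of SPNCRNA.232 by 7.42 ± 0.35. The exception was SPNCRNA.485 on chromosome III (0.15 ± 0.43, adjusted p = 0.914). With 5 min of heat 1 of the 14 changed in WT (SPNCRNA.362, -0.72) and 1 in the libraries labelled clr4Δ (SPNCRNA.365, 1.49). The first call was lost in a fit of these groups alone (adjusted p = 0.195), and the second with a pseudocount of 5 (0.228) and without replicate 2 labelled clr4Δ at 5 min (0.0508). With the replicate number as a block, 1 changed in WT and 2 rose in the libraries labelled clr4Δ, SPNCRNA.364 (1.03, 0.0386) beside SPNCRNA.365 (0.00798). Of all 6150 genes of that table, 152 were higher and 27 lower at 0 min. The number lower was 8 to 16 with any 1 library left out. The count of 179 was 540 (321 higher, 219 lower) with the replicate number as a block and 105 with a filter of 10 times the minimum signal. With heat the second table gave 666 genes risen and 675 fallen in WT of series RNA2, and 708 and 745 in the libraries labelled clr4Δ. With table totals alone the splits were 443 and 850 and 485 and 848, and with the block the totals were 2341 and 2665.

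**Figure D3:**
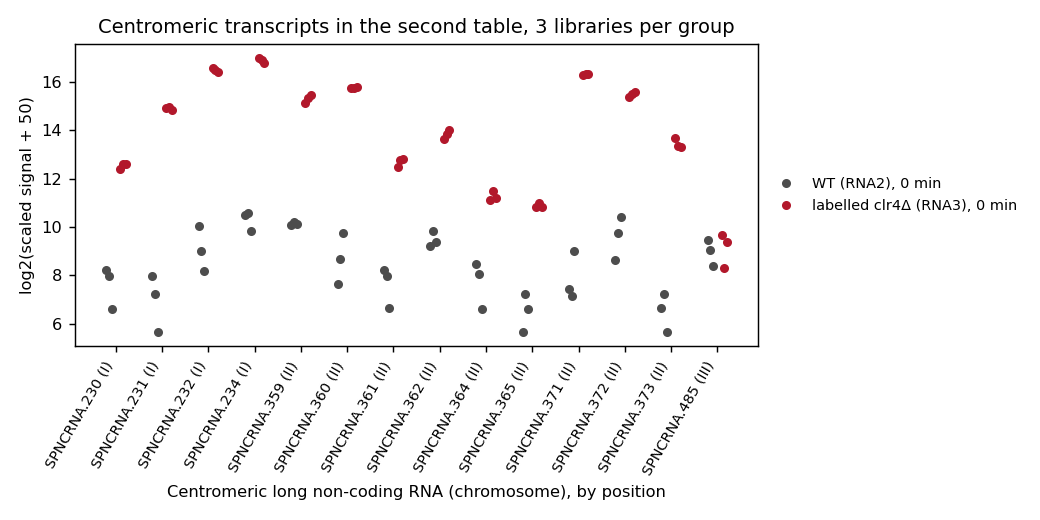
Log2 of the scaled coverage signal plus 50 (y axis) of 14 centromeric long non-coding RNAs (x axis) at 0 min, in the 3 WT libraries of series RNA2 and the 3 libraries labelled clr4Δ, as points. SPNCRNA.371 has a mean of 7.86 in WT and 16.3 in the libraries labelled clr4Δ, and SPNCRNA.485 has 8.96 and 9.11.

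WT was measured at 0 and 5 min in both series, which allowed them to be compared. At 0 min chaperone genes were higher in series RNA2 than in RNA1, 19 of 26 with 2 lower (20 and 2 when adjusted over the list alone), among them ssa1 by 2.19 ± 0.26, psi1, an Hsp40, by 1.61 ± 0.17 and aha1 by 1.13 ± 0.12. Their rise with 5 min of heat was smaller in series RNA2 for 20 of 26 (21 when adjusted over the list alone), with ssa1 at -3.14 ± 0.35, psi1 at -2.46 ± 0.23 and fes1 at -1.67 ± 0.15. The rise was smaller too for 19 of 30 Atf1-dependent genes (21 smaller and 1 larger when adjusted over the list alone) and 8 of 10 trehalose and glycerol genes (8). Of the MBF genes 10 of 17 (11) were higher in series RNA2 at 0 min. The set calls on the rise held with an estimated correlation for chaperones (4.81e-04) and trehalose and glycerol genes (0.0333), and not for the Atf1-dependent list (adjusted p = 0.0619 with an estimated correlation). At 0 min the call of chaperones (2.54e-14) gave an adjusted p = 0.0754 with an estimated correlation and that of MBF genes (1.15e-05) gave 0.10. In total 855 genes were higher and 602 lower in series RNA2 at 0 min, and 149 had a higher and 424 a lower response to 5 min of heat. With library totals alone the last split was 203 and 257, with the replicate number as a block the total was 1406, and a fit of these groups alone gave 335.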

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

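Some results, in 3 patterns, went beyond a plain reading of the labels, and each was weighed against explanations other than the one the label names. The test with meu6 and the use of the 0 min level for chaperones were chosen only after seeing the result. So was the use of library totals and of a single WT series, which had been planned as settings, to weigh these patterns. No test for a single deviating library was made in groups of 3, but each library was left out in turn.

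Counts of clr4 were higher in the libraries labelled clr4Δ than in WT, by 1.89 ± 0.07 at 0 min. A swap of samples could give this, but 9 of the 9 libraries so labelled had a mean log2 CPM of 50 subtelomeric genes (3.57 to 3.82) above that of every other library at 0, 2.5 or 5 min (1.80 to 2.89), which argues against mislabelled samples. Reads from parts of the locus left in place, or from the marker, are the other explanation. The gene meu6, whose interval on the other strand (chromosome II, 454108 to 456553) lies inside that of clr4, differed by -1.102 (adjusted p = 3.28e-04), so part of the locus may have been lost while other parts are read more. The neighbour SPNCRNA.1362 was higher by 1.45 ± 0.32 (0.61 and no longer called against WT of series RNA1 alone), and this reading could be settled by the coverage along the locus, not analysed here.

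Heat raised chaperone and Atf1-dependent genes less in series RNA2 than in RNA1, within a total of 573 genes whose response differed between the series. The median difference in response, series RNA2 minus RNA1, was -0.871 for chaperones and -0.989 for the Atf1-dependent list. For chaperones the level at 0 min was higher in series RNA2 by a median of 0.622 and the difference left at 5 min was -0.376. The larger part of their difference thus lay in the 0 min level, though 18 of 26 genes were still lower at 5 min. For the Atf1-dependent list the level at 0 min differed by 0.14 and that at 5 min by -0.625, so the larger part lay at 5 min. In each gene the difference in response is the 5 min difference less the 0 min one. This split therefore cannot show whether a higher start limits the rise. Library scaling could also shrink a response, but with library totals alone the median differences in response were -0.782 and -0.889, which argues against it. No biological cause was tested.

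The libraries labelled atf1Δ, pcr1Δ and clr4Δ each had a response that differed from WT, for 553, 444 and 162 genes. The WT series used as reference could produce this, since series RNA1 and RNA2 differ. Of the 162 genes, 1 was also called against series RNA2 alone. The lower response of the libraries labelled clr4Δ may thus come from series RNA1. At 0 min these libraries differed from WT in 230 genes with series RNA2 and in 2316 with series RNA1 as reference. By this count series RNA2 was the nearer reference for them. Of the 553 and 444 genes, 128 and 124 were called against series RNA2 alone, which argues against the choice of WT series as the whole cause for the labels atf1Δ and pcr1Δ. Series RNA3 holds no WT library, so a response particular to it cannot be tested against WT. Yet its libraries labelled clr4Δ raised the Atf1-dependent list by a median of 1.336, near the 1.348 of WT of series RNA2. The medians for the labels atf1Δ and pcr1Δ were 0.298 and 0.151. For this list these values argue against a loss shared by all libraries of series RNA3. Other differences between the libraries of that series cannot be told apart from the deletions. The 9 numbered replicates were also split in all 84 ways, in fits of these replicates alone that treat both WT series as 1 group, so that the series difference adds to the spread and counts differ from those above. This gave the label of atf1Δ the place 2 of 84 (294 genes, highest other 1608) and that of pcr1Δ 2 of 84 (215, highest other 1650). Each label also sets series RNA3 apart from WT, so these ranks cannot tell a deletion from a series difference. For clr4Δ this edgeR fit called 0 genes with the real labels (highest other 1520), so 84 of 84 splits gave as many and chance cannot be excluded in it, whereas the fit of all libraries called 162, with 971 genes at an unadjusted p under 0.05. In all 3 cases the highest other split set series RNA1 apart.

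The responses of the libraries labelled atf1Δ and pcr1Δ differed from each other for 2 genes. In the second table, 13 of 14 centromeric long non-coding RNAs were higher in all 3 libraries labelled clr4Δ at 2.5 min than in all 3 of WT. By chance 10% of genes separate in 1 or the other direction, and these 14, picked after the values were seen, appear to share reads.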

How the results depend on the processing

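Without the 3 libraries with the highest share of ribosomal RNA, and with other pseudocounts, the settings were chosen only after seeing the result. The others were set before the data were examined. Of 193 counts under other settings 150 stayed within 1.5-fold of the value in the report and 43 did not. Of 201 counts with 1 library left out 174 stayed and 27 did not. No named gene changed direction. The larger of the higher and lower counts changed sides in several comparisons that were near even, and with library totals alone for WT at 5 min (991 higher, 2520 lower), 25 against 5 min (2767, 1069), 5 against 2.5 min (308, 457) and the libraries labelled clr4Δ at 5 min (642, 1018). The cause of these changes was not tested.

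With library totals alone the count for WT at 2.5 min fell to 71 and that of the clr4Δ response difference at 5 min to 81, while the atf1Δ and pcr1Δ responses differed for 4 genes. With DESeq2, 156 genes changed in the libraries labelled clr4Δ at 2.5 min and 4 differed between the atf1Δ and pcr1Δ responses. Fits of the contrasted groups alone gave 32 for WT at 2.5 min, 273 from 2.5 to 5 min, 55 and 1063 for the libraries labelled clr4Δ at 2.5 and 5 min, 50 for their response difference, 7 between atf1Δ and pcr1Δ, 1012 for clr4Δ at 0 min and 335 for the series difference in response.

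With the replicate number as a block the counts were 483 for WT at 2.5 min, 1557 from 2.5 to 5 min, 2817, 2648 and 582 for heat in the libraries labelled atf1Δ (5 min), pcr1Δ (5 min) and clr4Δ (2.5 min), 1107, 1088 and 900 for the atf1Δ, pcr1Δ and clr4Δ response differences at 5 min, 11 between atf1Δ and pcr1Δ, 1406 between WT series, and 540, 2341 and 2665 in the second table. For atf1Δ the numbers 2 and 3 did not pair in the check, so its block counts are uncertain. For pcr1Δ they paired no better than an unequal pair, so its block counts are uncertain as well. Block results at 0 min, such as the 540, rest on numbers not checked between strains or series. The block also added set calls for phosphate uptake (WT at 5 min, adjusted p = 0.0187, and at 25 min, 0.0129) and the Atf1-dependent list in the libraries labelled atf1Δ (0.0153), among others, and lost that of phosphate uptake for clr4Δ at 0 min (0.0563).

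Series RNA2 alone gave 1678 genes for WT at 5 min. With series RNA1 or RNA2 alone as WT the response differences numbered 994 or 128 for atf1Δ, 1016 or 126 for pcr1Δ and 846 or 1 for clr4Δ, and the differences of clr4Δ at 0 min 2316 or 230. With the other deletions as reference, 1412, 972 and 3116 genes differed at 0 min for atf1Δ, pcr1Δ and clr4Δ. Without the 3 libraries with the highest ribosomal RNA share, heat changed 1212 genes in the libraries labelled atf1Δ, and 307 (atf1Δ), 95 (clr4Δ) and 1 (atf1Δ against pcr1Δ) response differences were left. A filter of 10 times the minimum signal left 105 genes in the second table at 0 min. With an estimated correlation 23 of 120 set calls held. DESeq2 on the second table was not run, as its values are a signal.

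Leaving out 1 library gave 48 to 168 genes for WT at 2.5 min, 477 to 1004 from 2.5 to 5 min, 40 to 120 for the libraries labelled clr4Δ at 2.5 min, 64 to 265 for their response difference, 827 to 1576 for clr4Δ at 0 min and 0 to 2 between atf1Δ and pcr1Δ. Among the response differences, the genes with a higher response numbered 39 to 223 for atf1Δ and 29 to 162 for pcr1Δ.

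Named genes held in most settings. Among the exceptions, with WT of series RNA2 alone, were the response differences of ssa1 (-0.32) and atf1 (-0.34) for pcr1Δ, of pho84 (1.06 for atf1Δ and 0.775 for pcr1Δ) and of ddr48, hsp16 and ssa1 for clr4Δ (-0.58, -1.47 and -1.10), none with adjusted p under 0.05. With the other deletions as reference, ste11 (pcr1Δ, 0.28) and ssa1 (clr4Δ, 0.45) lost their calls at 0 min. So did eno102 (atf1Δ and pcr1Δ), where the differences stayed large (-4.23 and -4.35) and their SE rose to 2.55. The call of gsf1 between atf1Δ and pcr1Δ was lost without any of 10 libraries, though its difference stayed between -0.793 and -0.916. That of hsp16 gained a call with the block, DESeq2, library totals, or a fit of these groups alone.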

Other observations

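Long non-coding RNAs drew attention at 25 min of heat and at the centromeres, beyond the comparisons of the design. The tests of long non-coding RNAs against other genes were chosen only after seeing the result, while those on overlapping genes and on early genes were set before.

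At 25 min, 492 of 1083 long non-coding RNAs were higher in WT, or 45.4%, against 31.6% of protein-coding genes (Fisher's exact p = 1.12e-17). Reads shared with an overlapping gene may explain this: the 110 that overlap no gene were called higher at odds of 1.01 against protein-coding genes (31.8%), while of the 973 that overlap a gene 47% were. Yet those 110 had a median change of 0.276, against -0.047 for protein-coding genes, and 15.5% of them were lower, against 38.3%, so a shift that does not come from shared reads stays open. The 2 kinds of long non-coding RNA were not tested against each other, and strand-resolved coverage could separate the explanations.

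Centromeric long non-coding RNAs were higher at 0 min in the libraries labelled clr4Δ in 13 of 14 cases in the second table, against 139 of 6136 other genes (Fisher's exact p = 1.05e-20). This is consistent with loss of silencing at the repeats in these libraries, whose clr4 counts were higher than in WT. The smallest rise among the 13 was that of SPNCRNA.364 (3.56 ± 0.47). Loss of Clr4 activity would also fit the subtelomeric genes, where 9 libraries of 9 stood apart from the rest. The class was picked after its values were seen, and the genes of a repeat appear to share reads. The 13 are thus not independent, and Fisher's exact p overstates the evidence.

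Genes that had risen by 2.5 min might have been expected to need Atf1 and Pcr1 more than genes that rise later. Of 70 early genes 69 were also higher at 5 min. Their median response difference, against WT of series RNA1 alone, was -1.32 in the libraries labelled atf1Δ and -1.18 in those labelled pcr1Δ, against -0.45 and -0.44 for 804 later genes. Compared within strata of like rise at 5 min, the mean difference was 0.03, with permutation p = 0.859 and 0.862. The size of the rise may thus account for the gap. An effect of earliness is not excluded, since this test compares means, not medians, within only 5 strata.

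The libraries were also regrouped at random or in every way for the other comparisons. For WT at 5 min the labels ranked 1 of 100 splits (3124 genes, highest other 2506). At 0 min, in fits of the 9 libraries alone whose counts differ from the report, they ranked 1 of 84 for atf1Δ (1905, highest other 410), 1 of 84 for pcr1Δ (1589, highest other 481) and 2 of 84 for clr4Δ (172, highest other 1639, with series RNA1 apart). These 0 min labels also set series RNA3 apart, so their ranks cannot tell a deletion from a series difference. With 3 against 3 there are 10 splits, too few for a share under 0.05. In these the labels ranked 1 of 10 for WT at 2.5 min (107 genes, highest other 22), WT at 25 min (4156, 1), 25 against 5 min (3584, 0), 5 against 2.5 min (834, 316), heat at 5 min with the labels atf1Δ (1846, 0), pcr1Δ (1691, 0) and clr4Δ (1865, 67), clr4Δ at 2.5 min (97, 44), and the series difference at 0 min (1457, 0). They ranked 1 of 10 as well for the second table at 0 min (179, 0) and with heat (1341, 0 in WT and 1453, 0 with the label clr4Δ). Response differences were split in fits of the 6 numbered replicates alone, each as a block, so their counts differ from the report's. There the labels ranked 1 of 10 for the series difference in response (1141, 0; 573 in the report) and for the atf1Δ against the pcr1Δ response (20, 3; 2 in the report), and 10 of 10 for the clr4Δ response at 2.5 min (0 genes with edgeR, highest other 6; in the report 0, with 74 at an unadjusted p under 0.05 and 0 with DESeq2).

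These values leave open which part of the 0 min differences from WT belongs to the deletion, since series RNA3 holds no WT library. With the other deletions of that series as reference, 1412 genes differed for atf1Δ, of which 1220 were also called against WT, and 972 for pcr1Δ, of which 757 were. These shared genes do not settle the cause, since the other deletions enter that reference and the libraries of series RNA3 were not alike. The 10 most counted genes took 6.50 to 7.59% of the counts with the label clr4Δ and 8.48 to 10.56% with atf1Δ or pcr1Δ. Under the same change the count for clr4Δ was 3116, against 1519 with WT, from reference libraries that themselves differ from WT in 2747 and 2363 genes. A WT library grown beside each deletion would separate the explanations.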
